A study of Mus musculus with 6 samples.

How the data were processed

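The series measured RNA from mouse leukemia cells that carry Hoxa9 and Meis1, the gene pair that drives this leukemia model, and a floxed Jmjd1c gene that the Cre recombinase can delete. Per the labels, 3 libraries are controls and 3 come from cells that received Cre by retrovirus together with the red fluorescent marker Tomato. Tomato-positive cells were sorted on day 6 after infection, per the series' design text. The cells came from 3 leukemic mice and grew in 10% serum with 10 ng/ml of interleukin 3. What the control cells received is not given in the sources used here. The columns of the table carry either the mark CRE or the mark MIT, not the titles in the labels. Those marked CRE were taken as the Cre group, since the design text says that Cre was delivered, and those marked MIT as controls, since the labels name no other group. The meaning of MIT is not given in the sources used here, so this assignment is inferred, and the direction of every fold change rests on it. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit; the selection of RNA and the strand setting are not given in the sources used here.

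The deposited table holds a signal for each of 33068 RefSeq transcripts in 6 libraries: the authors divided the read count of a transcript by a single scaling factor per library. STAR, featureCounts, DESeq and the mm10 build are listed in the submitters' processing notes, without versions or roles. All deposited values were whole multiples of the smallest value above 0 in their column: 100% lay within 0.001 of a whole number of reads, and the largest distance was 2.32e-06. In the Cre library of mouse A this step was 0.994, so close to 1 that it looks like rounding, but its values carried the same exact multiples as the other columns. The whole reads could thus be recovered for all 6 libraries. The deposited scaling differed from median-of-ratios factors computed on those reads by a relative 4.38e-12 at most. These values are called normalized counts below.

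Isoforms of a gene shared reads in this table: 4914 gene symbols had several transcripts, 13919 in all. Each symbol was therefore represented by its transcript with the highest mean over the 6 libraries, which left 24063 genes. This choice was made after the table was seen. Counted this way, the libraries held 33364778 to 47631201 reads. Genes with a mean of at least 10 normalized counts were tested, 13095 in all. The 95% limits printed for a share of reads in a single library are Wilson binomial limits and cover counting error only, since reads without molecular identifiers are not independent molecules. Genes with near-identical copies, and genes that overlap others, can share reads and are named as uncertain where this applies.

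The Cre group was compared with the control group by limma (version 3.58.1, R 4.3.3) with a mean-variance trend, on log2 of the normalized count plus 1. Fold changes are on that scale and understate the change of low genes. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The level of Jmjd1c was also compared by an exact two-sided permutation test, in which 3 libraries against 3 cannot give a p below 0.1. Before the data were examined, 28 gene lists were written from general knowledge, and none was taken from these samples. Each list with at least 3 tested members was tested by limma's camera with a preset correlation of 0.01 between genes, then again with an estimated correlation, and by limma's fry. The design foresaw limma for normalized values. The count tests, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads of all 6 columns, were alternatives.

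The column names carry the same 3 numbers in each group. Because the cells came from 3 mice, and because control and Cre libraries with the same number deviated together from their group means (correlations of 0.444, 0.449 and 0.702 across genes, against -0.508 to 0.246 for other pairs), these numbers were taken to pair the libraries by mouse, and the mice are called A, B and C in the order of their numbers. Which of the titled replicates each column is, is not given in the sources used here. The comparison was fitted without a replicate block, as fixed before the data were examined. The fit with the mouse as a block is printed beside results where it changes a call or moves a count by over 1.5 times. In limma each gene borrows variance from all genes, and the weight of this share is its prior degrees of freedom. These were 60.2 with the block (median) and 3.69 without it. Very small p-values with the block therefore rest mostly on variance pooled across genes, not on the 3 pairs alone.

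The genes named in the text follow a rule fixed before the data were examined. Jmjd1c, Hoxa9 and Meis1 are always given. Of genes past the threshold whose groups did not overlap and whose mean was at least 50, the 12 with the largest rise and the 12 with the largest fall are named. For each list, up to 4 members are named: those with the smallest p among members that passed, or else those with the highest mean. Members of the list of Jumonji and other histone demethylases that passed are named as well, and genes without a usual symbol may be left out. Any other gene in the text was chosen after its values were seen. Coordinates are those of the GENCODE vM21 annotation on GRCm38, the assembly also called mm10.

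The alternatives comprised another pseudocount, another filter on low values, TMM or recomputed median-of-ratios scaling, other variance models, the count tests, the replicate block and leaving out each library in turn. Chosen after the data were seen were a test of every transcript, the replicate block without a mouse, the block in edgeR, and the block with an estimated correlation. The method was tested on simulated data for the Jmjd1c comparison, with counts drawn for the 13095 genes and 200 of them changed. In counts without a mouse effect, limma without a block recovered 75% of the genes changed by 1 on the log2 scale. It recovered 95% of those changed by 2, and 8.11% of its calls were false. The fit without a block was not tried on counts with a mouse effect, so these rates do not hold for libraries paired by mouse. With a simulated mouse effect, whose size was not taken from these data, and the block, limma recovered 96% and 98%, and 5.83% of its calls were false. Figures were drawn with matplotlib 3.10.9. No column of per-sample values was left out.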

Results

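RNA from 6 libraries of mouse Hoxa9/Meis1 leukemia cells was analysed, 3 from control cells and 3 from cells in which Cre was expressed to delete Jmjd1c, a member of the Jumonji family of histone demethylases. The libraries paired by mouse, with the mice called A, B and C here. The control libraries held 47631201, 33364778 and 35621367 reads for these mice in that order, and the Cre libraries held 39234679, 37200348 and 39790922. A read was worth 0.804 to 1.14 normalized counts, so 3 reads, the floor of detection, corresponded to 2.41 to 3.42 normalized counts. The ribosomal RNA precursor gene Rn45s took 1.11% (1.11 to 1.12) of the reads in the Cre library of mouse B, the lowest share. It took 3.10% (3.09 to 3.10) in the control library of mouse C, the highest.

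The comparison addressed what the loss of Jmjd1c does to gene expression in this leukemia. Jmjd1c RNA (chromosome 10, 67096125 to 67256326, plus strand) was lower with Cre in each of the 3 mice, but most of it remained. The control group had 4627 ± 241 normalized counts and the Cre group 3186 ± 392 (SD, n = 3 each), 31.1% less. Within the mice, the Cre library held 60.2% (mouse A), 76.2% (mouse B) and 70.3% (mouse C) of its own control. Hoxa9 (chromosome 6, 52223100 to 52231089, minus strand), a driver of the model, had 75559 ± 8648 normalized counts in controls and 71913 ± 14495 with Cre. Its partner Meis1 (chromosome 11, 18879817 to 19018985, minus strand) had 110470 ± 8951 and 114872 ± 20762.

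Jmjd1c passed the test across all genes with a log2 fold change of -0.54 (SE 0.10, limma adjusted p = 0.0361), and with the replicate block its adjusted p was 4.25e-08. The exact permutation test of its normalized counts gave p = 0.1, two-sided, the smallest that 3 libraries against 3 allow. Hoxa9 (log2 fold change -0.09, adjusted p = 0.787) and Meis1 (0.04, adjusted p = 0.895) differed by less than the spread between libraries. Reads of any Hoxa9 or Meis1 copy introduced to drive the model would be counted with those of the cell's own gene. These levels therefore do not show what the cell's own Hoxa9 and Meis1 genes did. The other isoform of Jmjd1c shared its reads with the one given. Reads were counted over the whole transcript and the deleted part is not given in the sources used here, so the level does not measure the share of deleted alleles. Without any 1 of the libraries other than the Cre library of mouse C, the adjusted p of Jmjd1c lay between 0.0943 and 0.136, and the call was lost.

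**Figure D1:**
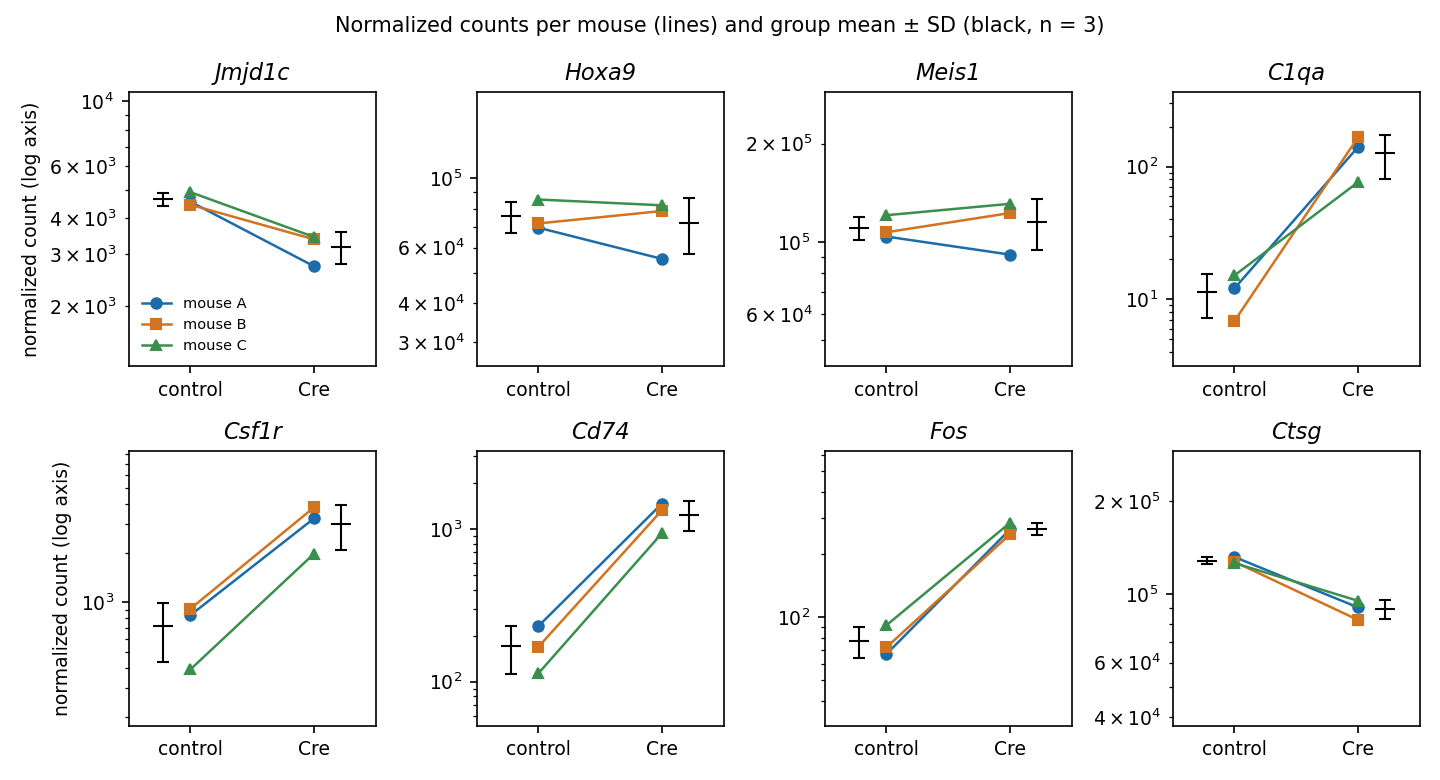
Normalized counts (log axis) of 8 genes in control and Cre libraries, with a line for each mouse and the group mean ± SD in black (n = 3). Jmjd1c and Ctsg are lower with Cre in each mouse, C1qa, Csf1r, Cd74 and Fos are higher in each, and the lines of Hoxa9 and Meis1 do not share a direction.

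Of the genes past the threshold without a replicate block, 322 rose and 29 fell with Cre, and the 12 largest rises included the macrophage list genes C1qa, C1qc and Clec4a1. Marcks (chromosome 10, 37133375 to 37138920, minus strand), which encodes an actin-regulating substrate of protein kinase C, rose from 5.56 ± 3.15 to 95.9 ± 36.2 normalized counts (log2 fold change 3.91, adjusted p = 0.0108). Spint1, a serine protease inhibitor, rose to 258 ± 150 normalized counts (log2 fold change 3.61, adjusted p = 0.0235). The complement genes C1qa and C1qc rose by 3.37 and 3.05, and the cholesterol exporter Abca1 rose from 12.6 ± 5.95 to 120 ± 1.64 (3.24). Among genes with a mean of at least 50, the fall was largest for Cth, the gene of cystathionine gamma-lyase in cysteine synthesis, which went from 471 ± 111 to 156 ± 70.9 (log2 fold change -1.66, adjusted p = 0.0466).

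Of the 13095 genes tested, 351 passed the threshold: 322 rose and 29 fell, and 156 of the rises and 6 of the falls were at least 2-fold. The remaining genes with the largest rises were Klk1b11 (log2 fold change 2.98), Mir5107 (2.97), AI607873 (2.96), Clec4a3 (2.93), Cd74 (2.88), Ifi204 (2.86) and Clec4a1 (2.80). Of these, AI607873 and Ifi204 belong to the interferon-inducible Ifi200 family, and Clec4a3 and Clec4a1 encode C-type lectin receptors of myeloid cells. Mir5107 (chromosome 18, 60812076 to 60812163) lies inside Cd74 (60803848 to 60812652) on the same strand, so its reads cannot be separated from those of Cd74. Klk1b11 belongs to a family of near-identical kallikrein genes, and its reads are uncertain for that reason. The other large falls were Zcchc14 (-1.55), the adhesion receptor Eltd1 (-1.49), Armcx4 (-1.11), the homeobox gene Six4 (-1.09), Fam174b (-0.91), Glyat (-0.88), Plekhh2 (-0.88), the protocadherin Pcdh7 (-0.71), the inositol transporter Slc5a3 (-0.66), the carbonic anhydrase Car12 (-0.64) and B4galt4 (-0.59).

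The groups did not overlap for 3579 genes, 1865 higher and 1714 lower with Cre. They were 27.3% of those tested, where chance gives 10% for libraries that can be exchanged freely, which libraries paired by mouse are not. With the replicate block, 3077 genes passed, 1892 higher and 1185 lower, so that rises made up 61.5% of the calls, against 91.7% without the block, and these included all 351. Leaving out single libraries moved the count without the block, from a fit that ignores the pairing by mouse. It was 0 without the Cre library of mouse A, where 2059 genes had an unadjusted p under 0.05. It was 8 without the Cre library of mouse B, and 3032 without that of mouse C. Without the control library of mouse A, B or C it was 54, 53 or 109.

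**Figure D2:**
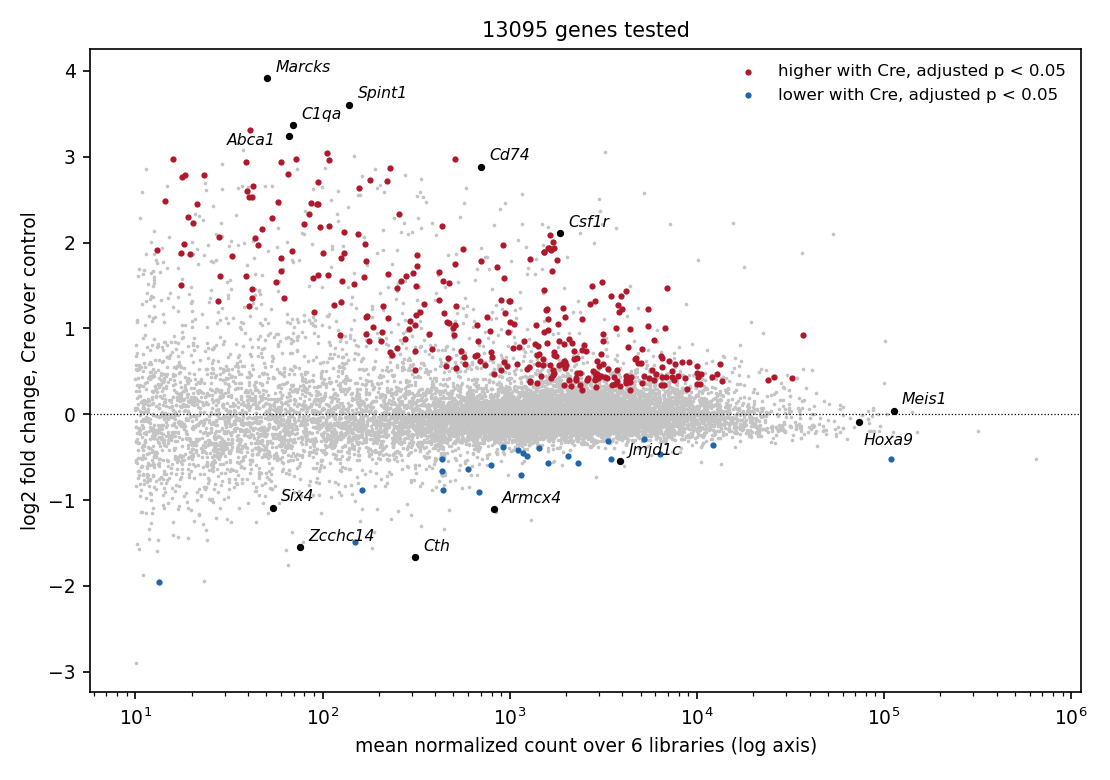
Log2 fold change of Cre over control against the mean normalized count over 6 libraries (log axis) for the 13095 genes tested. Red points are the 322 genes that rose and blue points the 29 that fell at an adjusted p under 0.05, and black points mark named genes from Cth (-1.66) to Marcks (3.91).

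Of 30 measured monocyte and macrophage genes, 16 rose and 14 did not pass, and 25 were higher in 3 of 3 mice. With the replicate block 23 rose and 1 fell. The scavenger receptor Msr1 rose from 42.5 ± 7.63 to 272 ± 58.6 normalized counts, C1qb from 47.1 ± 13.2 to 313 ± 60.1, the lysosomal protease Lgmn from 48.1 ± 10.7 to 213 ± 44.6 and C1qa from 11.3 ± 4.18 to 127 ± 46.1 (n = 3). Among members chosen after their values were seen was Csf1r, the receptor for macrophage colony-stimulating factor (chromosome 18, 61100598 to 61132149, plus strand). It had 714 ± 282 normalized counts in controls and 3002 ± 928 with Cre, and was higher in each mouse. The lysosomal marker Cd68 (log2 fold change 0.14, adjusted p = 0.401), Apoe (-0.06, adjusted p = 0.852) and the monocyte gene Ly6c2 (-0.01, adjusted p = 0.987) did not pass. The list's median log2 fold change was 1.63. Camera called it higher (adjusted p = 1.73e-15), and it had an adjusted p = 0.157 with an estimated correlation. The count adjusted over the list alone was 21 higher.

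Of 30 measured granulocyte genes 0 rose and only Ctsg, a protease of primary granules, passed by limma, although 12 were higher and 2 lower at an unadjusted p under 0.05. EdgeR called 1 higher and 1 lower, and DESeq2 6 and 2. The list had the highest median, 1.74 (mean 1.33). Ctsg fell from 128514 ± 3078 to 89468 ± 6405 (log2 fold change -0.52, adjusted p = 0.0431), and 29 did not pass. There were 7 rises and 2 falls when adjusted over the list alone. With the replicate block 23 rose and 3 fell, and 23 were higher and 5 lower in 3 of 3 mice. Mmp8, a collagenase chosen after its values were seen, had a log2 fold change of 3.06 and 5731 ± 3374 normalized counts with Cre. Its adjusted p by limma was 0.0632, and 2.52e-39 with the block, a value that rests mostly on variance pooled across genes. Its log2 change within the mice was 2.76, 3.19 and 3.23. The calgranulin gene S100a9, also chosen afterwards, had 27638 and 30512 normalized counts in the controls of mice A and B but 4523 in that of mouse C. Its Cre libraries held 109022, 126460 and 21872 in that order. Of other primary granule genes chosen afterwards, Mpo (log2 fold change -0.31, adjusted p = 0.61, and 0.00126 with the block), Prtn3 (-0.05, adjusted p = 0.862) and Elane (0.07, adjusted p = 0.907) did not pass without the block. Camera called the list higher (adjusted p = 0.000129), with an adjusted p of 0.59 when the correlation was estimated, and fry did not call it (adjusted p = 0.4).

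Antigen presentation genes of the dendritic cell list rose in part. Cd74, the invariant chain of MHC class II, rose from 171 ± 58.8 to 1241 ± 273 normalized counts (log2 fold change 2.88, adjusted p = 0.00729), and the integrin gene Itgax (1.55) and the class II gene H2-Eb1 (1.27) rose as well. The other 9 of the 12 measured members did not pass, 4 members rose when adjusted over the list alone, and 7 rose with the replicate block. The list's median was 0.22. Its camera adjusted p was 0.000178, and 0.157 with an estimated correlation, although that estimate was 0.0138, close to the preset 0.01.

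Interferon and inflammatory genes were among those that rose. Of 36 measured interferon response genes 11 rose, among them Oas3 from 5064 ± 341 to 7999 ± 668 normalized counts, Ifit1 from 163 ± 28.2 to 466 ± 117, Rsad2 from 453 ± 15.5 to 1417 ± 435 and Gbp2 from 255 ± 33.1 to 488 ± 46.4, and 25 did not pass. When adjusted over the list alone 26 rose, and 26 rose and 1 fell with the replicate block. The list's median was 0.39 (camera adjusted p = 1.83e-11, and 0.244 with an estimated correlation). Of 24 NF-kB and inflammatory genes 5 rose: the chemokine gene Ccl3 from 645 ± 72.2 to 1363 ± 182, the prostaglandin synthase gene Ptgs2 from 41.3 ± 3.83 to 159 ± 43.1, the inflammasome gene Nlrp3 (log2 fold change 0.94), the feedback inhibitor Tnfaip3 (0.92) and Ccl4 (1.19), chosen after its values were seen. The other 19 did not pass, while 22 rose when adjusted over the list alone and 21 with the replicate block. Their median was 0.86 (camera adjusted p = 2.15e-12, and 0.259 with an estimated correlation).

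The immediate early genes Fos and Jun rose. Of 29 genes of the Ras-ERK feedback and immediate early list, 9 rose, led by Fos from 76.8 ± 13.2 to 266 ± 17.0 normalized counts (log2 fold change 1.79, adjusted p = 0.00729), Fosl2 (1.00), Zfp36 (1.11) and Jun (1.07). The feedback genes Etv4 (-1.56, adjusted p = 0.127), Spry4 (-1.49, adjusted p = 0.131) and Dusp4 (-1.03, adjusted p = 0.122), chosen after their values were seen, did not pass over all genes. They were the 3 falls, beside 17 rises, when adjusted over the list alone, and each fell with the replicate block (adjusted p = 1.1e-12, 8.8e-08 and 0.00221). In the list 17 rose and 5 fell with the block. The list's median was 0.44 (camera adjusted p = 2.63e-06, and 0.157 with an estimated correlation). In the IL-3 and JAK-STAT5 list 5 of 23 genes rose: the cytokine signaling inhibitor Socs1 (0.59), the cytokine gene Osm (0.56), the phosphatase gene Ptpn6 (0.39), the receptor subunit Csf2rb2 (0.59) and the kinase gene Lyn (0.68), the last chosen after its values were seen. This became 14 when adjusted over the list alone and 13 with the block. The median was 0.29 (camera adjusted p = 7.92e-06, and 0.157 with an estimated correlation).

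Of 32 p53 target and apoptosis genes 3 rose. They were the cell cycle inhibitor Cdkn1a, from 3774 ± 261 to 5110 ± 218 normalized counts, the pro-apoptotic Bcl2l11 (log2 fold change 0.66) and Zmat3 (0.73). The other 29 did not pass, 16 rose and 1 fell when adjusted over the list alone, and 17 rose and 1 fell with the block. The median was 0.23 (camera adjusted p = 7.46e-06, and 0.157 with an estimated correlation). Of 18 hypoxia genes only the stress-responsive Ndrg1 rose, from 3779 ± 110 to 6407 ± 117 (adjusted p = 0.00377). Of the hypoxia genes 4 rose when adjusted over the list alone, and 9 with the block. The median was 0.22 (camera adjusted p = 2.61e-05, and 0.259 with an estimated correlation).

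The lists of amino acid, mitochondrial and ribosomal genes had medians below 0, with 1 member, Cth, past the test. Of 27 ATF4 and amino acid response genes Cth fell and 26 did not pass, 8 fell and 2 rose when adjusted over the list alone, and 19 fell and 2 rose with the replicate block. The serine synthesis gene Psat1 (log2 fold change -0.58, adjusted p = 0.109) and the asparagine synthetase gene Asns (-0.44, adjusted p = 0.132), chosen after their values were seen, were lower in 3 of 3 mice. They did not pass over all genes and passed when adjusted over the list alone and with the block (adjusted p = 3.73e-08 and 4.08e-06). The list's median was -0.38 (camera adjusted p = 0.0013, and 0.59 with an estimated correlation). Of 37 oxidative phosphorylation genes, 29 Myc and ribosome biogenesis genes and 43 cytosolic ribosomal protein genes, limma called 0. At an unadjusted p under 0.05, 7, 9 and 10 of them were lower, and with the block 7, 12 and 6 fell. The counts adjusted over the list alone were 0 for each list, edgeR also called 0, and DESeq2 called 2, 1 and 1 lower. The highest genes of these lists were Atp5b (-0.23), Atp5a1 (-0.15), Cox4i1 (-0.16) and Uqcrc1 (-0.23), then Ncl (-0.23), Npm1 (-0.31), Myc (-0.07) and Mybbp1a (-0.16), then Rpl4 (-0.25), Rplp0 (-0.13), Rpl8 (-0.19) and Rps3 (-0.15). The medians were -0.15, -0.19 and -0.18 (camera adjusted p = 5.28e-06, 3.32e-06 and 1.16e-08), and the adjusted p was 0.59 for each with an estimated correlation.

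Genes of the Hoxa9-Meis1 programme and of progenitors were not called as a list (median 0.01, camera adjusted p = 0.941). Of 27 measured members 3 rose: the transcription inhibitor Id2 from 569 ± 95.5 to 1425 ± 283 normalized counts, the cyclin gene Ccnd3 (log2 fold change 0.35) and the adhesion receptor gene Cd44 (0.61). The other 24 did not pass, 3 rose and 1 fell when adjusted over the list alone, and 6 rose and 6 fell with the block. Of 20 histone demethylase genes, Jumonji members with Kdm1a and Kdm1b, only Jmjd1c passed, and it fell. With the block 5 rose, and 19 of the 20 did not pass without it. This list's median was 0.11 (camera adjusted p = 0.0599). Of 44 cell cycle genes Ccnd3 and the E2F gene E2f2 (0.33) rose and 42 did not pass. The count adjusted over the list alone was the same, 2 higher. With the block 2 rose and 8 fell, and camera then called the list lower (adjusted p = 0.0296, against 0.0631 without the block and 0.737 with the block and an estimated correlation). The median was -0.09.

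Of the markers of other cell types only Mitf passed without the block. Of 10 mast cell and basophil genes Mitf rose (log2 fold change 0.76), and 3 rose and 4 fell with the block. Adjusted over the list alone, 2 rose and 1 fell (median -0.22, camera adjusted p = 0.824). For 11 erythroid and megakaryocyte genes, 5 B cell genes, 5 T and NK cell genes and 9 stromal and fibroblast genes, limma called 0, and at an unadjusted p under 0.05 it had 3, 0, 1 and 2 higher and 0, 0, 1 and 0 lower. EdgeR called 1, 0, 0 and 0 higher and DESeq2 2, 0, 0 and 2, neither with a gene lower. The block called 4, 0, 1 and 3 higher, and 1 T and NK cell gene lower. Among these, the platelet receptor gene Gp1bb (log2 fold change 2.10), Car2 (0.86), Col1a1 (1.44) and the cytokine receptor gene Il7r were higher and the granule gene Nkg7 (-1.09) was lower in 3 of 3 mice. The erythroid and megakaryocyte list passed camera with the block (adjusted p = 0.0384, against 0.0892 without it and 0.337 with the block and an estimated correlation). Adjusted over the list alone, 1 erythroid and megakaryocyte gene rose, and 1 T and NK cell gene rose and 1 fell. Collagen and matrix genes stood out in the Cre library of mouse B: Col1a1 had 155 normalized counts there and 61.7 or fewer in the other 5 libraries, and the matrix gene Sparc, chosen after its values were seen, had 119 against 7.55 or fewer. The camera adjusted p of the stromal list was 0.148 (median 0.96), that of the B cell list 0.941 (median -0.16) and that of the T and NK cell list 0.898 (median -0.13). None of the 9 eosinophil genes in the table reached the minimum mean of 10, and they were not tested.

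Metabolic and stress genes outside the lists above did not pass. Among 23 glycolysis, 24 cholesterol biosynthesis, 15 fatty acid synthesis, 20 unfolded protein response, 14 heat shock and 20 histone genes, limma called 0. At an unadjusted p under 0.05 there were 6, 0, 0, 1, 0 and 1 higher and 0, 1, 4, 1, 0 and 0 lower in that order. EdgeR called 1 glycolysis gene higher and 1 cholesterol gene lower. DESeq2 called 3 glycolysis genes, 1 unfolded protein response gene and 1 histone gene higher, and 1 cholesterol and 3 fatty acid genes lower. With the block 5, 1, 1, 1, 0 and 1 rose and 0, 1, 5, 1, 2 and 0 fell. Adjusted over the list alone, 2 glycolysis genes rose, 1 cholesterol gene fell and 4 fatty acid genes fell. Gapdh, a glycolytic enzyme gene, had 92453 ± 3520 normalized counts in controls and 92422 ± 1342 with Cre. The fatty acid synthase gene Fasn had a log2 fold change of -0.16, the chaperone genes Hspa5 and Hsp90ab1 0.04 and -0.21, and the histone gene H2afx -0.13. The camera adjusted p values were 0.148, 0.941, 0.113, 0.941, 0.201 and 0.898. The median, mean and camera direction differed in sign for the B cell, cholesterol biosynthesis and unfolded protein response lists. In all, 13 of the 27 lists tested were called by camera, 9 higher and 4 lower. With an estimated correlation 0 were called, and 5 had an unadjusted p under 0.05. For the dendritic cell, p53 and Ras-ERK lists the estimates were 0.0138, 0.0236 and 0.0247, close to the preset 0.01. Their lost calls therefore cannot come from correlation between genes alone. When camera estimates the correlation, it also tests on the few residual degrees of freedom of the 6 libraries, which makes p-values larger. Fry called these lists higher (adjusted p = 0.00842 for each). The granulocyte list had an estimate of 0.764.

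**Figure D3:**
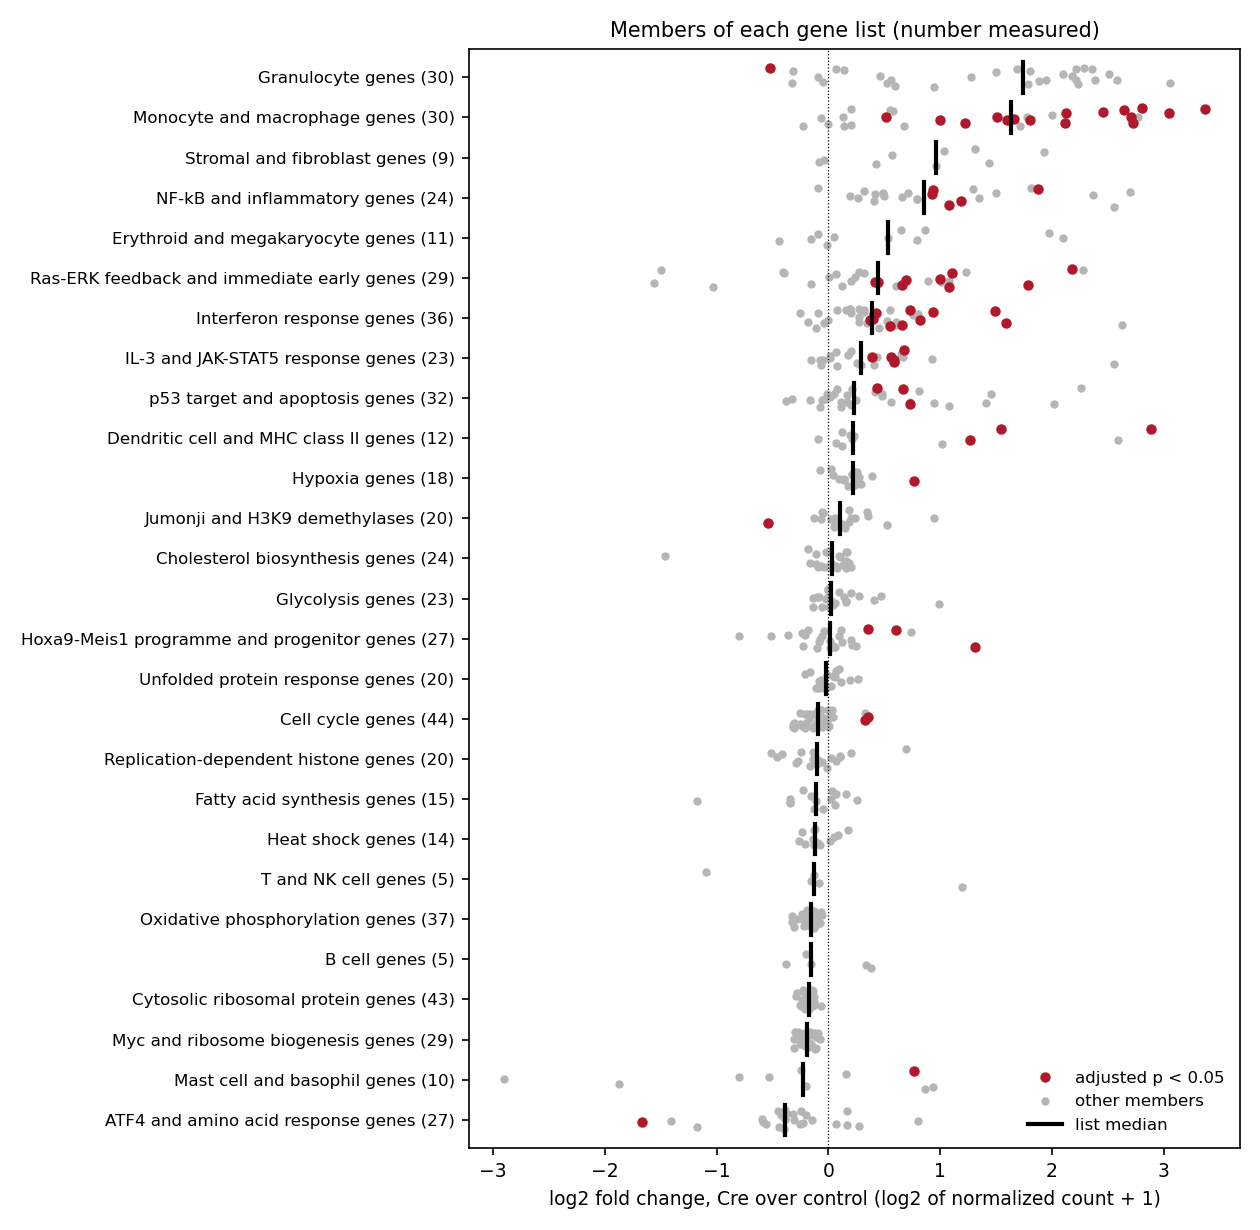
Log2 fold change of Cre over control for the measured members of 27 gene lists, with the number measured in parentheses. Red points passed at an adjusted p under 0.05, grey points did not, and black bars are list medians, from -0.38 for ATF4 and amino acid response genes to 1.74 for granulocyte genes.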

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

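The tests of depth and of stromal genes in this part were chosen after the result was seen. In the Cre library of mouse B, 936 genes had a read and had none in the other 5 libraries, where the same count was 120 to 190. Most of these 936 were near the floor: their median was 1 read, the highest had 49, and 23 had 5 or more. They lay below the minimum mean of 10, so the comparison did not use them. Collagen and matrix genes, of which Col3a1, Sparc and Col1a2 had reads elsewhere and were tested, led what stood out there, and the stromal list's median change was 0.91 in mouse A, 2.02 in mouse B and -0.14 in mouse C. Col3a1 had 114 normalized counts against 6.47 or fewer elsewhere, Sparc 119 against 7.55, Col1a2 99.4 against 5.40 and tenascin C (Tnc) 50.8 against 0. A greater depth is argued against, since with every library thinned to the 33364778 reads of the smallest this one still had reads for 16580 genes and the others for 15300 to 15461. RNA of fibroblasts or other stromal cells stays open: with the next library taken as at least 3.42 normalized counts (3 reads), 4 of the 15 stromal and fibroblast genes were at least 3 times above it, where the test needed 5, as were 0 of 83 genes of 5 other cell types. Without that minimum 6 of the 15 were, Dcn and Kdr added, but so were 7 of the 83, among them 16.7% of the erythroid and megakaryocyte and 11.8% of the T and NK cell list, above the 10% that the test allowed, so both counts leave it open. Of the 15 genes, 5 were at 10 or more in every control and 1 is in another list. The sort for Tomato would remove cells without the vector, but the purity of the sorted cells was not tested. No biological explanation was tested.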

How the results depend on the processing

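Another pseudocount, filter on low values or scaling, robust variances, edgeR without a block and a test of every transcript kept the number of genes called Jmjd1c versus control within 1.5 times of 351 (314 to 453), and those that give a value for Jmjd1c kept its fall. The count moved to 3077 with the replicate block, 1246 with DESeq2 (10420 genes had no adjusted p), 182 with variances without a trend and 162 with a 2-fold minimum. Alternatives chosen after the data were seen gave 2989 for edgeR with the block, and 1710, 1925 and 3054 for the block without mouse A, B or C. Leaving out each library in turn gave 0 to 3032 genes, 0 without the Cre library of mouse A and 3032 without that of mouse C, with fewer samples behind each fit. For Jmjd1c these fits gave log2 fold changes of -0.60 to -0.44 (adjusted p = 0.00463 to 0.136), past the threshold only without the Cre library of mouse C, and variances without a trend gave -0.54 (adjusted p = 0.0926). Of 108 named genes 55 had a call. All 55 lost it without the Cre library of mouse A, 54 without that of mouse B, and 38, 43 and 29 without the control library of mouse A, B or C. Without the Cre library of mouse C, 0 lost it and 12 other named genes gained a call. With the block and mouse A, B or C left out, 0 of the 55 lost the call. Variances without a trend took the call from 18. Of the 13 gene lists called, 8 were called by fry, all higher, 0 with an estimated correlation and 0 with the block and an estimated correlation (3 with an unadjusted p under 0.05). The 13 lists kept camera's call with each library left out. The block added the erythroid and cell cycle lists and changed no other list's call. Beyond what fewer samples and the block's own construction show, the cause was not tested. Depth limits genes near 3 reads a library: those with a mean under 10 were not tested, but tested genes had fewer reads in single libraries.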

Other observations

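The gene families in this part, the weighing of the 2 patterns below and their tests were chosen after the values were seen; the splits of the libraries were planned. Most members of these families did not pass. Of 9 Toll-like receptor genes 3 rose (7 with the replicate block): Tlr7, a sensor of single-stranded RNA, from 149 ± 16.4 to 493 ± 9.91 normalized counts (n = 3), Tlr9, a sensor of unmethylated DNA, from 51.8 ± 6.31 to 163 ± 28.0, and Tlr2, from 673 ± 45.8 to 1432 ± 400. Their adjusted p values by limma were 0.00377, 0.0119 and 0.0391. Of 7 Ms4a genes 3 rose, Ms4a4c (log2 fold change 2.47), Ms4a6d (2.53) and Ms4a6c (0.99). With the block 4 rose and 1 fell, Ms4a3, from 27527 ± 856 to 22008 ± 1317 (adjusted p = 0.0655, and 0.00343 with the block). Of 21 C-type lectin genes Clec4a3, Clec4a1 and Clec5a rose (8 with the block). Of 28 ABC transporter genes 4 rose (11 rose and 3 fell with the block), among them the cholesterol exporters Abca1 and Abcg1, the latter from 1457 ± 34.1 to 2698 ± 333. Of 5 stefin A genes, near-identical copies that can share reads, limma called 0 (0 at an unadjusted p under 0.05) and the block called 5 higher, with a median log2 fold change of 2.18.

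The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 351 genes and the highest of the others 0 by limma, with 47 to 2512 genes at an unadjusted p under 0.05; 1 of 10 splits gave as many. Of the 4 splits that part all 3 pairs, 1 gave as many genes with the block, the real one with 3077, and the highest other gave 0; these too are too few. For gene lists, 2 of 10 splits gave as many calls by camera as the real 13: the highest other gave 15, and the others 4 to 15. That split set the control libraries of mice A and B with the Cre library of mouse C against the rest, and it gave 15 lists with the block as well, as many as the real one. It keeps the real contrast in mice A and B and reverses it only in mouse C, so its calls can carry the Cre effect. The number of lists called by camera with a preset correlation therefore neither sets the real grouping apart nor speaks against it.

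The granulocyte and macrophage lists had medians above 0 in each of the 3 mice. Without the block limma called 0 of 30 granulocyte genes higher (12 at an unadjusted p under 0.05, 1 by edgeR, 6 by DESeq2) and 16 of 30 macrophage genes. With the block 23 granulocyte genes rose and 3 fell, and 23 macrophage genes rose and 1 fell. In 3 of 3 mice, 23 granulocyte and 25 macrophage genes were higher, and 5 and 1 were lower. With an estimated correlation the camera adjusted p was 0.59 and 0.157. The scaling between libraries is argued against, since a scaling shifts all genes of a library alike and the macrophage list's median lay 1.65 above the median of all genes. Macrophages mixed into the Cre libraries cannot be told apart from a change in the leukemia cells: the granulocyte list's median of 1.56 or more in each mouse only restates what was seen, and both predict that macrophage genes with a mean under 100 in controls were higher in 3 of 3 mice, as 12 of 13 were. The sort for Tomato would remove cells without the vector, but how pure the sorted cells were was not tested. Of the macrophage list Cd68 (log2 fold change 0.14), Apoe (-0.06) and Ly6c2 (-0.01) did not pass. Their levels in controls, 7090, 528 and 76058 normalized counts, may hide a small share of other cells, but how large a share was not computed for any of them. The loss of Jmjd1c, which the design names, stays open as a hypothesis and cannot be told apart from Cre or its vector, because no Cre-treated cells with intact Jmjd1c were analysed here (the p53 target and apoptosis list had a median of 0.23), and mature granulocytes among the sorted cells were not tested.

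In both libraries of mouse C the granulocyte list was lower than in the other mice, by a median log2 difference of -1.36 in the controls and -1.68 with Cre, and 29 of its 30 genes were lower in this control than in both others. Reads lost to Rn45s would lower all genes of a library alike, which the scaling divides out, so they are argued against for a difference in 1 list. Before scaling, the difference in the Rn45s share can shift a gene by a log2 value of -0.0292 at most. This test could hardly have come out otherwise, and RNA quality was not tested. A less mature leukemia in mouse C may lie behind this and stays open: across 13095 genes, which are not independent replicates, the difference of its control from the other controls correlated at -0.421 with the Cre effect, and the same difference among the Cre libraries at -0.573. The Cre effect is built from the same libraries, no value without a relation was computed, and this rests on 1 mouse, so the correlations decide nothing. The changes with Cre in mouse C followed the mean of the other mice with a slope of 0.674, against 0.927 for mouse A and 1.13 for mouse B (11606 genes), and whether these slopes differ was not tested.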
